A study of Mus musculus with 12 samples.

How the data were processed

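RNA sequencing was carried out on 12 single-cell-derived clones of conditionally immortalized mouse granulocyte-monocyte progenitors. The progenitors came from fetal livers of C57BL/6 embryos at embryonic day 15.5, per the labels. They were held in an immature state by a retroviral fusion of the estrogen receptor hormone-binding domain with the transcription factor Hoxb8 (ER-Hoxb8). The fusion is active while estradiol is in the medium. Cells were grown with stem cell factor (about 50 ng/ml) and 0.5 µM estradiol, and RNA was taken under these conditions. These conditions alone do not show that every clone stayed undifferentiated, and neutrophil genes were high in wild-type clone 2D. There were 6 wild-type clones and 6 clones lacking Tafazzin, an X-linked acyltransferase that remodels the mitochondrial phospholipid cardiolipin. Clone titles carry a number (1 and 2 in wild type, 3 and 4 in knockout) before the clone letter, with 3 clones per number. The labels do not say what the number means. If it marks an embryo or a parent line, clones that share it are not independent, and p-values over 12 clones are too small.

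The deposited values were raw counts of reads per Ensembl gene, in a separate file for each clone. Per the submitters' processing notes, STAR, HTSeq and edgeR were used and the genome build was mm9, with no versions given. The file names state that reads were counted without regard to strand. Reads from a gene and from an overlapping gene on the other strand can therefore not be separated. Tafazzin overlaps the start of Dnase1l1 on the opposite strand in the GENCODE annotation used for names. The annotation release behind the deposited counts is not stated. The last 5 lines of each file are HTSeq totals that name no gene and were left out of library sizes and tests. Among all records, 43.6% ± 0.611 (SD, n = 12) were assigned to reads aligned to more than 1 place, 3.55% ± 0.301 lay outside genes and 1.59% ± 0.0373 were ambiguous. Reads shared between near-identical genes are therefore mostly missing from the counts. Of 37583 gene identifiers in the deposited count files, 32860 were matched to a symbol and chromosome from a gene name table and GENCODE mouse release M21. That release belongs to a later build than mm9, so only names, chromosomes, neighbouring genes and transcript sequences were taken from it, and no coordinates are given. No mitochondrially encoded gene was in the count table, and the list of these genes was not analysed here. The gene appears under its older symbol Taz.

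Library totals in genes ran from 18970252 to 27431544 counts. A count of 3, taken as the limit that a count of 0 allows, corresponds to between 0.109 and 0.158 CPM, the usual count scaled to library size. It covers counting error only, as PCR copies are not independent molecules. Clone values are given in CPM after TMM scaling in the tests of genes and in plain CPM elsewhere.

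The main test was the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, on the deposited counts of all 12 clones, with TMM normalization, filterByExpr by genotype and Benjamini-Hochberg adjustment over all genes tested. Genes with an adjusted p under 0.05 were called. The standard error (SE) of a log2 fold change was its absolute value over the square root of F. A prior count of 2 was used for log2 CPM values of clones. It was not set for log2 fold changes, which used the default of edgeR's fit. Clones of different title numbers were compared within each genotype by the same test. A model with 4 groups of 3 clones gave the 4 knockout-minus-wild-type pairs of title numbers, and genes called with the same sign in all 4 were counted. The 4 pairs share libraries and are not independent.

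A total of 31 gene lists was fixed before the data were examined, covering stress responses, mitochondria, lipid metabolism, apoptosis, the cell cycle and the blood lineages, and 30 had at least 3 tested members. For each, called members were counted with adjustment over all genes and adjusted over the list alone. Lists were also tested with camera of limma 3.58.1 (preset correlation 0.01, and an estimated correlation) and with fry. A further test was chosen after the data were seen. It used a score per clone, the mean log2 CPM of a list's members, compared between genotypes by an exact two-sided permutation test over all assignments of 12 clones into 6 and 6. The smallest p it can give is 0.00216.

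Named genes followed a rule fixed before the data were examined. They were Tafazzin; up to 8 rises and 8 falls that were largest among called genes with mean log2 CPM of at least 2, no overlap between genotypes and a call in all 4 pairs; up to 4 members of each list with the smallest adjusted p; and a fixed set of stress, apoptosis, lineage and sex-linked genes. Predicted genes were left out.

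Tests were tried on simulated counts for the real genes with known changes. Changed genes were drawn only from those above a minimum mean CPM, which was higher for the 4 pairs, so genes of low level are not covered. Clones were simulated as independent, so the counts do not cover likeness between clones that share a title number. In the simulated comparison of 6 with 6 clones (11708 genes), 15 of 50 genes changed in a ratio of 5 to 4 were called, as were 38 of 50 changed 1.5-fold, 45 of 50 changed 2-fold and 47 of 50 changed 4-fold, with 10 calls among unchanged genes. In the simulated comparison of numbers 1 and 2 (11748 genes) 0 of 50 genes changed in that ratio, 18 of 50 changed 1.5-fold, 36 of 50 changed 2-fold and 42 of 50 changed 4-fold were called, with 6 calls among unchanged genes. For numbers 3 and 4 (11650 genes) the counts were 0, 6, 38 and 43 of 50, with 3 among unchanged genes. In the simulated 4 pairs (11814 genes), 30 of 40 genes changed 2-fold in both knockout numbers were recovered, and 0 of 40 changed in number 3 alone. The latter result was nearly fixed in advance, as those genes held no change in the pairs of number 4.

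Alternatives were RLE size factors, the Wald test of DESeq2 1.42.0, no filter or a stricter filter on low counts, limma voom with and without the title number as a correlated block, counts summed by title number, each clone or each title number left out, sex-linked genes left out, and a minimum absolute log2 fold change of 1. A covariate for the level of Hoxb8 was added after the data were seen. The correlation of clones with the same title number estimated for the block was -0.169. The mean Pearson correlation of log2 CPM was 0.960 between clones of the same title number, 0.964 between numbers of the same genotype and 0.954 between genotypes. The libraries of no pair were copies of each other, as the lowest chi-square per degree of freedom over 66 pairs was 14.2. Figures were drawn with matplotlib 3.10.9.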

Results

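Gene expression was measured in 12 clones of ER-Hoxb8 granulocyte-monocyte progenitors from mouse fetal liver, 6 wild-type and 6 Tafazzin-knockout. ER-Hoxb8 is an estradiol-dependent fusion protein that keeps such progenitors dividing without maturation. Wild-type clones are named 1A, 1B, 1C, 2D, 2E and 2F, and knockout clones 3G, 3H, 3I, 4J, 4K and 4L. Reads counted in genes averaged 24969227 ± 2150523 (SD, n = 6) in wild type and 21197723 ± 2016313 (n = 6) in knockout, a difference in depth between genotypes (exact two-sided permutation p = 0.0152, adjusted over 6 library measures 0.0304). The lowest totals were 18970252 counts in 3G, 19778119 in 3H and 19913625 in 4L, and the highest was 27431544 in 1B. The totals of the remaining clones were 26071215 in 1A, 21966954 in 1C, 23288919 in 2D, 26829138 in 2E, 24227590 in 2F, 23572337 in 3I, 23658158 in 4J and 21293849 in 4K. All 12 clones expressed the Y-linked genes Ddx3y, Kdm5d and Eif2s3y, so both genotypes are male.

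Tafazzin (Taz, ENSMUSG00000009995, chromosome X) checked the genotype labels. Its level was 39.2 CPM ± 2.58 (SD, n = 6) in wild-type clones and 3.35 CPM ± 0.685 (n = 6) in knockout clones, an 11.7-fold difference. Every wild-type clone lay between 37.1 and 43.9 CPM and every knockout clone between 2.21 and 4.08 CPM, from 856 to 1190 counts and from 44 to 87 counts. Knockout clones thus kept a low but countable signal. Counts per exon were not analysed here and Dnase1l1 overlaps the gene, so the values do not show whether this signal came from intact Taz transcript, and the fold difference is one of gene counts only. The log2 fold change of Taz was -3.54 (SE 0.13, adjusted p = 5.68e-08 by edgeR's quasi-likelihood test). Wwtr1, an unrelated gene that shares the alias TAZ, had at most 2 counts in each clone but 3G, where it had 9. Of the 14 tested genes next to Tafazzin on the X chromosome, 0 were called by edgeR, 3 had an unadjusted p under 0.05 and 2 were called by DESeq2. The smallest adjusted p among them was that of Lage3 (log2 fold change -0.36, SE 0.11, adjusted p = 0.0571), which passed the test without clone 1C (adjusted p = 0.0433).

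**Figure D1:**
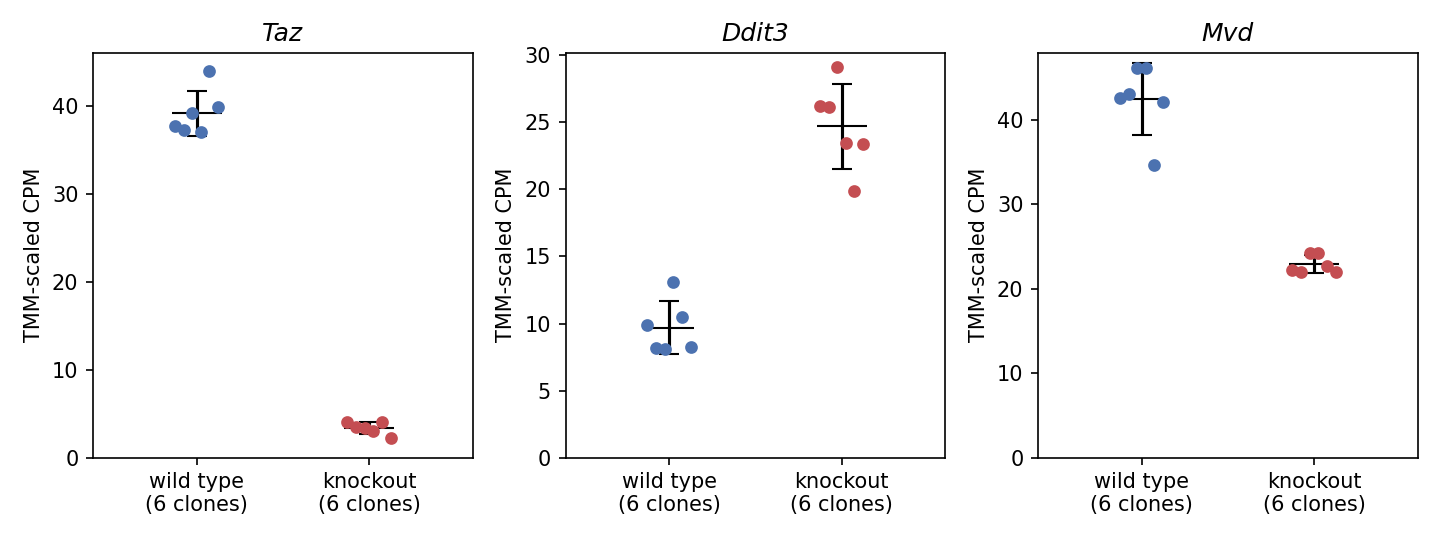
TMM-scaled CPM of Taz (Tafazzin), Ddit3 (the stress-response factor CHOP) and Mvd (a cholesterol synthesis enzyme) in each of the 6 wild-type and 6 knockout clones. Points are clones, horizontal lines are means and bars are 1 SD. For each of the 3 genes no knockout clone overlaps a wild-type clone.

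The central comparison asks how loss of Tafazzin alters the transcriptome of myeloid progenitors. Knockout clones had higher levels of genes of the ATF4-CHOP stress response and of p53 targets, and lower levels of cholesterol synthesis enzymes, while most genes that mark blood lineages did not pass the test. Largest changes were ranked among called genes with a mean log2 CPM of at least 2, no overlap between genotypes and a call in all 4 pairs of title numbers. The largest rise among these was that of Cox6a2, the heart and skeletal muscle isoform of a cytochrome c oxidase subunit. It went from 2.13 CPM ± 1.03 (n = 6) to 29.4 CPM ± 5.19 (n = 6), a 13.8-fold difference (log2 fold change 3.78, SE 0.31, adjusted p = 0.000163). Zmat3, an RNA-binding p53 target, rose 3.98-fold (2.13 CPM ± 0.490 to 8.50 CPM ± 2.67), and Trp53cor1, the p53-induced long noncoding RNA lincRNA-p21, rose 3.75-fold (3.48 CPM ± 0.971 to 13.03 CPM ± 1.82). Within the same set Ddit3, Psph, Pde4dip, Nf1 and Ifrd1 followed, with log2 fold changes of 1.35, 1.26, 1.22, 1.12 and 0.97. Nf1 encodes neurofibromin, a negative regulator of RAS. After Taz itself, the largest falls in that set were those of Mvd (log2 fold change -0.89), Lss (-0.69) and Nsdhl (-0.64), which encode enzymes of cholesterol synthesis, of Ucp2 (-0.61), a carrier of the inner mitochondrial membrane, and of Echdc1 (-0.58), an ethylmalonyl-CoA decarboxylase gene.

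Of 11819 genes tested by edgeR, 472 were higher and 466 lower in knockout, and 2806 had an unadjusted p under 0.05. Most changes were small, with a median absolute log2 fold change of 0.28 among called genes, and 69 higher and 37 lower genes changed at least 2-fold. In 566 called genes the genotypes did not overlap. The count of calls was unstable. When counts were summed by title number, 158 genes were higher and 116 lower. With the title number as a correlated block in voom 1171 were higher and 1125 lower, against 497 and 428 without the block. The correlation estimated for the block was negative (-0.169), so this fit makes no allowance for clones of the same number being alike. DESeq2 gave 800 and 830. Counts fell by over 1.5 times in at least 1 direction without clone 1B (303 higher, 305 lower), 3G (330 and 272), 3H (340 and 308) or 3I (294 and 276). Not every called gene named here was followed over the fits without single clones. Of the 65 that were, 12 near the threshold lost their call without at least 1 clone. These 12 kept their direction, with edgeR's adjusted p between 0.0501 and 0.0872. They were Atf4, Crls1, Sqstm1, Idh2, Cpt2, Eno1, Gpx1, Cxcr2, Itgb3, Igll1, Ccnb1 and Ccnb2. Some lost it in most of the 12 fits without a single clone: Cxcr2 in 10, Atf4 in 9, Cpt2 in 8, and Sqstm1 and Ccnb1 in 7 each.

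The ATF4-CHOP integrated stress response comprises genes for amino acid synthesis, amino acid import, tRNA charging and growth arrest that are induced by the transcription factors ATF4 and CHOP. Of its 35 tested members, 28 were higher in knockout and 0 lower (33 higher and 0 lower when adjusted over the list alone), with a median log2 fold change of 0.76. Ddit3, which encodes CHOP, rose from 9.67 CPM ± 1.97 to 24.7 CPM ± 3.16. Sesn2 rose from 48.0 CPM ± 13.6 to 136 CPM ± 11.7, and Psph, an enzyme of serine synthesis, from 38.9 CPM ± 5.82 to 93.0 CPM ± 15.6 (n = 6 per genotype). Trib3, a pseudokinase induced by CHOP, had the largest change of the members named here (log2 fold change 2.97, SE 0.53, adjusted p = 0.00655). Chac1, which degrades glutathione, rose by 1.85 on the log2 scale, Asns by 1.02, the seryl-tRNA synthetase gene Sars by 0.66 and Atf4 itself by 0.57 (adjusted p = 0.0344). The call of Atf4 was lost in 9 of the fits that left out a single clone. All 6 knockout clones had a higher mean log2 CPM over the list than any wild-type clone (7.20 ± 0.132 against 6.06 ± 0.366, exact permutation p = 0.00216, adjusted over 30 lists 0.00812). The preset-correlation camera test called the list (adjusted p = 9.66e-28), but not with an estimated correlation (adjusted p = 0.0837 with an estimated correlation, which was 0.489 between members).

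The chaperones and degradation machinery of the endoplasmic reticulum, targets of ATF6 and XBP1, were not called as a group. Of 32 tested members, Herpud1, Sel1l, Ern1 and Derl1 were higher and Hsp90b1, Pdia6, Creld2 and Syvn1 lower (clone scores exact permutation adjusted p = 0.55, camera adjusted p = 0.43). Hsp90b1, an abundant chaperone, fell from 1944 CPM ± 210.1 to 1534 CPM ± 89.1. The main chaperone gene Hspa5 stood at 2062 CPM ± 345.7 in wild type and 1769 CPM ± 166.9 in knockout (adjusted p = 0.221), and Xbp1 at 149 CPM ± 26.8 and 141 CPM ± 17.2 (adjusted p = 0.744).

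Targets of p53 rose in 10 of 21 tested members and fell in 0 (11 higher and 1 lower when adjusted over the list alone). These included Zmat3, the cyclin Ccng1 (162 CPM ± 10.1 to 225 CPM ± 16.2), the cell cycle inhibitor Cdkn1a (34.0 CPM ± 4.41 to 56.3 CPM ± 5.34) and Bbc3, which encodes the BH3-only protein PUMA (14.9 CPM ± 1.81 to 27.02 CPM ± 3.03). The list was called by camera with the preset (adjusted p = 8.24e-07) and the estimated correlation (adjusted p = 0.0185). All 6 knockout clones scored above every wild-type clone (exact permutation adjusted p = 0.00812). Trp53 itself was at 253 CPM ± 7.48 and 256 CPM ± 6.01 (log2 fold change 0.01, adjusted p = 0.789). Among 33 BCL-2 family members, caspases and apoptosis regulators, Bbc3, Bax and Bid were higher, and the lower genes included Casp6, Casp9 and Aifm1 (clone scores exact permutation adjusted p = 0.955, camera adjusted p = 0.74). Bcl2 (log2 fold change 0.65, adjusted p = 0.0609), Bcl2l11 (0.30, adjusted p = 0.0923), Bcl2l1 (0.03, adjusted p = 0.891) and Mcl1 (-0.02, adjusted p = 0.788) did not pass the test. Without clone 2E, Bcl2 passed edgeR's test (adjusted p = 0.0148). With all clones, DESeq2 called Bcl2 and Bcl2l11.

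Cholesterol synthesis fell almost as a whole. Of 22 tested members, 21 were lower in knockout and 0 higher (22 lower when adjusted over the list alone), with a median log2 fold change of -0.53. Mvd fell from 42.4 CPM ± 4.20 to 22.9 CPM ± 1.04, Nsdhl from 88.9 CPM ± 5.41 to 57.0 CPM ± 4.36, Lss from 94.5 CPM ± 5.55 to 58.4 CPM ± 6.05 and Dhcr7 from 119 CPM ± 9.30 to 81.6 CPM ± 6.34. All 6 knockout clones scored below every wild-type clone (mean log2 CPM 6.02 ± 0.080 against 6.54 ± 0.069, exact permutation adjusted p = 0.00812). Camera called the list with the preset (adjusted p = 7.92e-25) and with an estimated correlation (adjusted p = 0.0185).

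**Figure D2:**
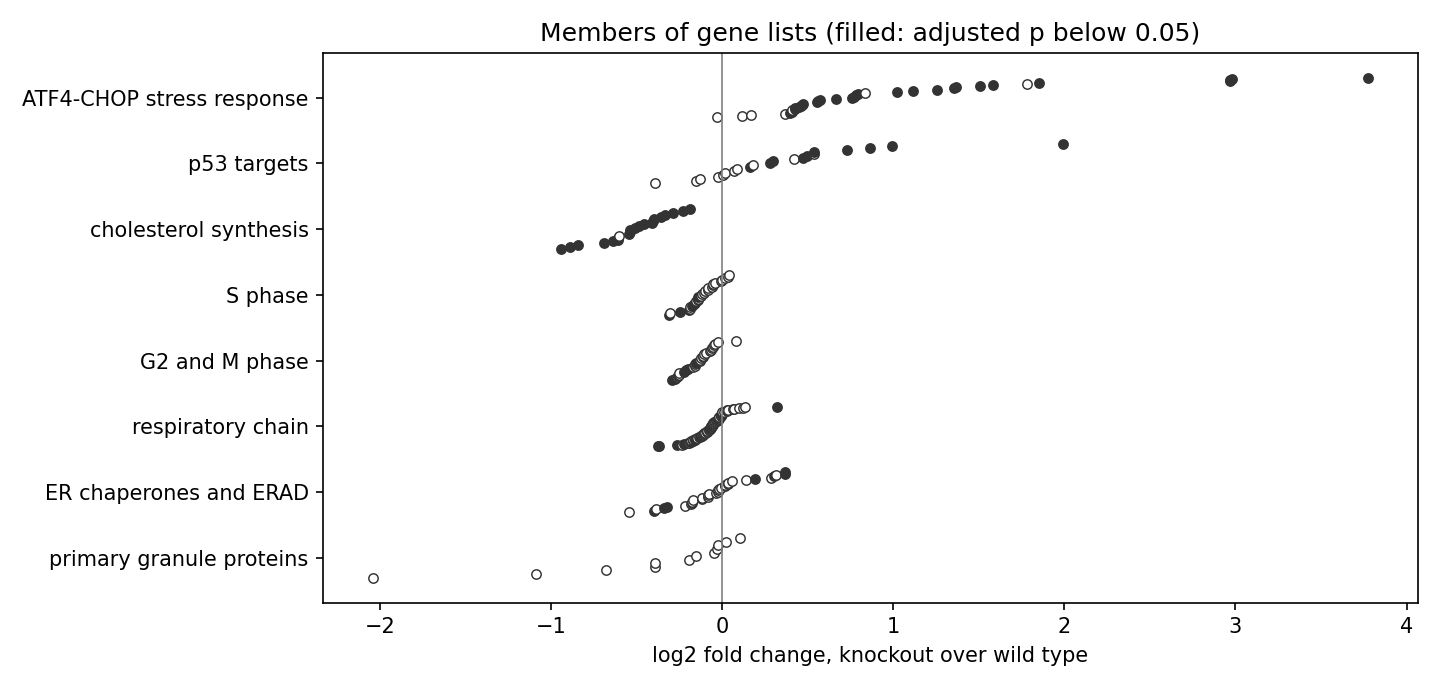
Log2 fold changes (knockout over wild type) of the tested members of 8 gene lists, ordered within each list. Filled points have an adjusted p below 0.05 and open points do not. Of the 35 ATF4-CHOP genes 34 lie to the right of 0 and 1 to the left, with 28 filled points, and all 22 cholesterol synthesis genes lie to the left, with 21 filled.

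Genes of the cell cycle were slightly lower. Of 28 S phase genes 8 were lower and 0 higher, among them Mcm4 (log2 fold change -0.19), Uhrf1 (-0.25), Gins2 (-0.31) and Mcm6 (-0.17), and all 6 knockout clones scored below every wild-type clone (exact permutation adjusted p = 0.00812). Of 28 G2 and M phase genes 7 were lower and 0 higher, including Kif20a (-0.28), Cdc20 (-0.29), Ccnb2 (-0.26) and Ccnb1 (-0.20), again with 6 of 6 clones below wild type (exact permutation adjusted p = 0.00812). With an estimated correlation, camera called neither list (adjusted p = 0.0508 for S phase and adjusted p = 0.395 for G2 and M phase).

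**Figure D3:**
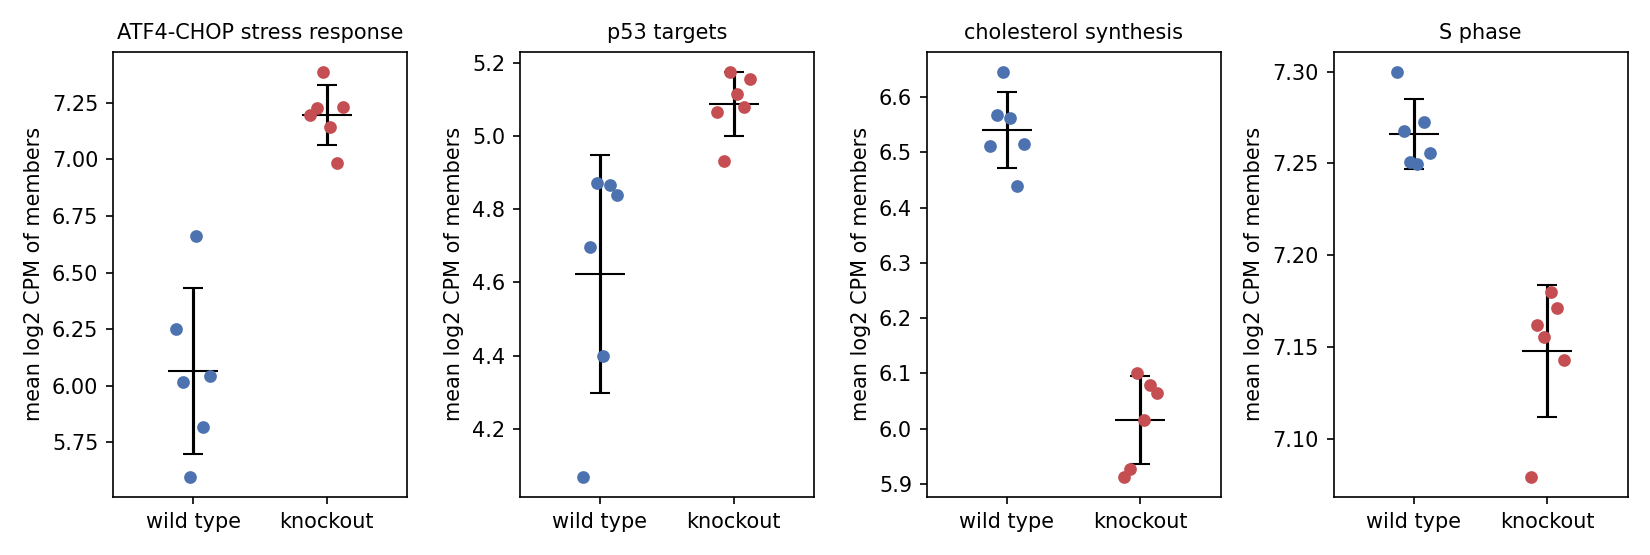
Mean log2 CPM of the tested members of 4 gene lists in each clone. Points are clones (6 per genotype), horizontal lines are means, bars are 1 SD, and the vertical axes differ and do not start at 0. In each of the 4 lists the genotypes do not overlap.

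Energy metabolism genes shifted little. In the nuclear-encoded respiratory chain and ATP synthase, 11 of 74 tested members were lower and 1 higher. The falls were small, as for Atp5k (log2 fold change -0.27), Atp5g3 (-0.18), Cox6b1 (-0.17) and Uqcrh (-0.13). Camera called the list (adjusted p = 1.47e-05), but not with an estimated correlation (adjusted p = 0.585), and the clone scores did not pass their test (exact permutation adjusted p = 0.092). Of 23 tricarboxylic acid cycle genes, Aco1 (-0.33), Fh1 (-0.17), Sucla2 (-0.12) and Idh2 (-0.22) were lower and 0 higher (exact permutation adjusted p = 0.026, camera adjusted p = 0.00165, and adjusted p = 0.395 with an estimated correlation). Of 24 glycolysis genes, Ldha (-0.38), Tpi1 (-0.34), Eno1 (-0.70) and Slc16a3 were lower and Pfkp (0.25) higher (exact permutation adjusted p = 0.0708, camera adjusted p = 0.0391, and adjusted p = 0.585 with an estimated correlation). Fatty acid oxidation had 2 lower genes of 21, Etfdh (-0.29) and Cpt2 (-0.21), and 0 higher (clone scores exact permutation adjusted p = 0.426, camera adjusted p = 0.116).

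Among 18 genes of cardiolipin synthesis and remodelling, Taz was lower and Crls1, the cardiolipin synthase gene, was higher (56.9 CPM ± 5.01 to 70.4 CPM ± 6.21, adjusted p = 0.0226). The fall of this list's score in 6 of 6 knockout clones (exact permutation adjusted p = 0.00812) includes Taz itself, and camera did not call the list (adjusted p = 0.313). Of 20 mitochondrial chaperones and proteases, Hspa9 was higher (996 CPM ± 109 to 1267 CPM ± 90.4) and 0 were lower (clone scores exact permutation adjusted p = 0.955, camera adjusted p = 0.717). Of 23 genes of mitochondrial dynamics, biogenesis and mitophagy, Sqstm1 (log2 fold change 0.31) was higher and Bnip3 (-0.54) lower (camera adjusted p = 0.28, clone scores exact permutation adjusted p = 0.0216). Of 30 NRF2 targets and antioxidant enzymes, Gclc (0.21), Gpx1 (0.38) and the ATF4 target Slc7a11 were higher, and Prdx1 (-0.21) and Tkt (-0.21) lower (clone scores exact permutation adjusted p = 0.754, camera adjusted p = 0.959).

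Lineage genes were mostly uncalled and varied widely between clones of the same genotype. In 10 lists 0 members were called by edgeR. Of their 106 tested genes 13 had an unadjusted p under 0.05 and 6 were called by DESeq2. These lists were the primary granule proteins, monocyte and macrophage, dendritic cell, progenitor regulator, erythroid, mast cell and basophil, eosinophil, fetal hepatocyte and stromal genes, and the neighbours of Tafazzin, and camera called none of them. Mpo, the myeloperoxidase gene of primary granules, was at 9998 CPM ± 2518 in wild type and 9811 CPM ± 3086 in knockout (adjusted p = 0.964). The gene Elane was at 231 CPM ± 320.5 and 56.0 CPM ± 52.6 (adjusted p = 0.263). Its wild-type mean rested on clones 2D (827 CPM) and 1A (372 CPM), and its log2 fold change of -2.04 became -0.996 without 2D. Kit was at 672 CPM ± 97.9 and 753 CPM ± 78.8 (adjusted p = 0.363), and Cd34 at 1712 CPM ± 414.3 and 1808 CPM ± 355 (adjusted p = 0.835). Irf8 (log2 fold change -0.39, adjusted p = 0.453) and Csf1r (0.99, adjusted p = 0.577) did not pass the test, and the sign for Csf1r turned without clone 3G (-0.69). In the secondary granule and mature neutrophil list, Cxcr2 was the 1 called member of 18, lower in knockout (log2 fold change -1.64, adjusted p = 0.0411). The call of Cxcr2 was lost in 10 of the fits that left out a single clone. Ltf had a log2 fold change of -3.51 (adjusted p = 0.263), which rested on clone 2D and became 0.65 without it. Of 9 megakaryocyte and platelet genes, the integrin gene Itgb3 was lower (-0.95, adjusted p = 0.0256). Of 12 lymphoid genes, the pre-B cell genes Cd79b (8.55 CPM ± 7.23 to 0.701 CPM ± 0.295) and Igll1 (10.1 CPM ± 17.2 to 0.859 CPM ± 0.150) were lower. The wild-type mean of the gene Igll1 rested on clone 2D (45.1 CPM, against 1.91 to 5.32 CPM in the other wild-type clones), and its log2 fold change of -3.55 became -1.87 without that clone (adjusted p = 0.00356). Their list's score was lower in 6 of 6 knockout clones (exact permutation adjusted p = 0.00812), while camera gave an adjusted p = 0.0318, and adjusted p = 0.226 with an estimated correlation. The list of 20 tested interferon-stimulated genes was not called by its clone scores (exact permutation adjusted p = 0.539) or by camera (adjusted p = 0.0975). Of 4 sex-linked reference genes Ddx3y was higher (103 CPM ± 4.47 to 120 CPM ± 3.44, adjusted p = 0.00313), the clone scores did not overlap (exact permutation adjusted p = 0.00812), and camera called the list (adjusted p = 0.0339, and adjusted p = 0.392 with an estimated correlation).

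Camera's preset correlation called 10 of 30 lists in total, and 2 with an estimated correlation, the p53 and cholesterol synthesis lists. Its preset count was no larger than random groupings of these clones can give, so a call by the preset test alone is weak evidence for a list. Fry, which asks whether the members of a list move one way on balance and makes no comparison with other genes, called 9 lists. Fry's adjusted p was 1.13e-05 for cholesterol synthesis, 1.73e-05 for p53 targets and 0.000203 for both the ATF4-CHOP and the S phase genes. Fry gave an adjusted p of 0.00169 for the cardiolipin list, 0.0155 for lymphoid genes and 0.0284 for sex-linked genes. For both the G2 and M phase genes and the tricarboxylic acid cycle fry's adjusted p was 0.0231. The cardiolipin list holds the knocked-out gene Taz itself, so its call is no separate evidence. The median log2 fold change of its tested members was -0.046.

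Genotype differences were also required to hold for each knockout title number against each wild-type number. By edgeR, 20 genes were higher and 6 lower in all 4 pairs, and all 26 were called over the 12 clones. The 6 lower genes were Taz, Mvd, Lss, Nsdhl, Ucp2 and Echdc1, and the higher genes included Cox6a2, Zmat3, Trp53cor1, Ddit3, Psph and Ccng1. Number 3 against 1 gave 121 higher and 70 lower genes, 3 against 2 gave 52 and 34, 4 against 1 gave 35 and 16, and 4 against 2 gave 25 and 11. When each pair was fitted separately, 0 genes were called in all 4. These separate fits called 93 genes for numbers 1 and 3, 3 for 2 and 3, 27 for 1 and 4 and 0 for 2 and 4.

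Title numbers within a genotype served as the background for these differences, in fits of 3 against 3 clones. Such fits called 0 of 50 simulated genes changed in a ratio of 5 to 4. Their counts can be set against the separate fits of pairs, not against the comparison of all 12 clones. In the model with 4 groups, where pairs share an estimate of the spread, numbers 2 against 1 and 4 against 3 also gave 0 called genes. Between numbers 1 and 2 in wild type, edgeR called 0 of 12008 genes, 257 had an unadjusted p under 0.05, and DESeq2 called 10. Between numbers 3 and 4 in knockout, edgeR called 0 of 11787 genes, 311 had an unadjusted p under 0.05, and DESeq2 called 17. The first principal component of log2 CPM (29.8% of variance) did not separate the genotypes and had the neutrophil genes S100a8, S100a9, Ngp and Ltf at one end. The second (15.1%) set the 6 knockout clones and wild-type clone 2D apart from the other 5 wild-type clones.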

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

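The Hoxb8 covariate, the comparison with matched genes and the tests of the signals in library 3G and of Uty in clone 1C were chosen after the data had been seen. Groups of 6 clones were examined for a clone far from the others, measured as its gap to the nearest clone over the group's range, against Dixon's critical value at 95%. Of 194 groups of values, 16 exceeded it, where chance gives about 1 in 20, or 9.7.

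Knockout clones combined higher ATF4-CHOP genes with lower cholesterol synthesis genes, with 49 called members in both lists together. Removing the trend on GC content and transcript length left the difference between the list medians (1.28 on the log2 scale, with values for all 57 tested members) at 1.00 of its size but was too small to decide (SD 0.0276), while such a bias is argued against by genes outside the lists matched on both properties, which differed between the lists by only 0.0041 of the difference of list medians. Clones differ in the level of the transgene, but with the Hoxb8 level as a covariate the share of the called members that kept their sign and at least 0.5 of their log2 fold change was 1. The state of the cultures at harvest would tie both lists together within genotypes, and this stays open, as the deviations of the clone scores from their genotype means gave an r too imprecise to decide (Pearson r = -0.0748, 95% interval -0.6457 to 0.5497 by Fisher's transformation, permutation p = 0.831; Spearman rho = -0.0699, permutation p = 0.839; n = 12; r = 0.220 without the 2 clones farthest from the median). A difference in culture that separates the genotypes as a whole stays open too, as the labels give no culture dates, and a consequence of Tafazzin loss is a hypothesis that these data leave standing.

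Library 3G of the knockout held transcripts of other tissues, with 18536 genes with a count, an outlier among knockout libraries (ratio 0.799), and 20 counts of Xist, the RNA of the inactive X chromosome of female cells, against at most 2 in any other library. RNA or reads of other tissues may be the source: in 3 tissues (liver, brain and skin) at least 3 markers lay 10 times above every other library, such as Alb (123 CPM), Hpx (21.8 CPM) and Apob (16.0 CPM) of liver, Gpm6a (7.80 CPM) and Ptprz1 (7.01 CPM) of brain and Krt14 (1.11 CPM) of skin. Fetal liver cells of the same embryo are argued against by 0.0858 Afp counts per 100 Alb counts, beside 211 counts of the adult liver gene Cyp2e1, and a liver programme switched on in this clone by 11 brain and skeletal muscle markers above that limit. The 633 genes at 10 times any other library made up 0.0922% of the counts of 3G, and the filter on low counts kept them out of the genotype comparison. Of the genes tested there, 23 were at least 2 times higher in 3G than in any other library, among them Csf1r (14.6 CPM against at most 3.21 CPM). Of these 23, 0 were called. Such a count is not particular to 3G, as it was 55 in 2D, 37 in 1A, 17 in 4K, 16 in 2E and 3 to 6 in the remaining clones. It stays open whether the RNA or the reads were mixed.

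Uty, a Y-linked relative of the histone demethylase gene Kdm6a, was nearly silent in wild-type clone 1C (16 counts, 0.728 CPM, against a mean of 54.4 CPM in the other wild-type clones; ratio 0.798). Loss of the Y chromosome is argued against by the mean level of Ddx3y, Kdm5d and Eif2s3y in 1C, 0.922 of that in the other wild-type clones. A longer silent or deleted stretch is argued against by its expressed neighbours Eif2s3y and Ddx3y, the lower of which was at 0.910. A change within Uty itself stays open and was not tested.

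Clone 2D lay far above the other wild-type clones in the neutrophil genes Ltf (ratio 0.976) and S100a9 (0.955), in Igll1 (0.921), in the stress genes Trib3 (0.736) and Ifrd1 (0.634), and in Hoxb8 (0.662). In wild type, Zmat3 was set apart in 1B (0.732) and Mvd in 2E (0.646). In knockout, Crls1 (0.637), Sel1l (0.790) and Ern1 (0.687) were set apart in 4K, Sars in 3I (0.659), Prg2 in 4J (0.735) and Csf1r in 3G (0.858). The share of records aligned to more than 1 place, which no comparison used, was 44.04% ± 0.542 in knockout and 43.24% ± 0.381 in wild type (exact permutation p = 0.0152, adjusted over 6 library measures 0.0304).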

How the results depend on the processing

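The Hoxb8 covariate was chosen after the data were seen. No gene called in the main comparison and under any of the alternatives that refit it changed sign between them. Taz kept its call under every alternative to the comparison of all knockout with all wild-type clones that tested it (not the one without sex-linked genes). In 4 separate fits of 3 against 3 clones it was called in 3, while title numbers 2 and 4 gave an adjusted p of 0.0857 with a log2 fold change of -3.69, and 0 genes were called there. Its log2 fold change ran from -3.61 to -3.44 when single clones were left out. Over 65 named genes called between genotypes, 1377 of 1685 combinations of gene and alternative kept the call, 308 lost it with the same direction, and 0 reversed. Of 100 splits of the 12 clones into 6 and 6 (462 are possible), 1, the real one, gave as many called genes as the 472 higher and 466 lower. The highest other gave 3, so chance can be excluded for this count only if the 12 clones are independent. If clones that share a title number are not, these splits cannot exclude it. For the 26 genes in all 4 pairs, 1 of 100 assignments, the real one, gave as many and the highest other gave 0. For the 10 lists called by camera, 22 of 100 splits gave as many, the highest 14 and the median of the others 7, so chance cannot be excluded for the number of lists. Within genotypes 3 against 3 clones make 10 splits, too few for a share under 0.05. The real values were 0 and 0, which 10 of 10 splits reach, and the highest others 1 in wild type and 4 in knockout. Splits that kept title numbers together but mixed genotypes called 0 genes each, and they are too few to exclude chance differences between title numbers. Genes higher and lower were 800 and 830 with DESeq2 and 271 and 280 with no filter on low counts. Voom gave 1171 and 1125 with a block, whose estimated correlation was negative, and 497 and 428 without it. Counts summed by title number gave 158 and 116 (183 shared with the main calls). An absolute log2 fold change of at least 1 left 69 and 37. With the Hoxb8 covariate 337 were higher and 265 lower. Leaving out single clones gave 294 to 558 higher and 272 to 535 lower genes. Leaving out title number 1, 2, 3 or 4 gave 76, 338, 51 or 107 higher and 72, 248, 33 or 77 lower genes, with 9 clones in each fit. Higher ATF4-CHOP genes numbered 22 to 31 without single clones, 7 without number 1, 5 without number 3, 11 without number 4, and 12 with the limit on log2 fold change. Lower cholesterol synthesis genes numbered 18 to 21 without single clones, 10, 8 and 11 without numbers 1, 3 and 4, and 0 with that limit. Higher p53 targets numbered 7 to 10 without single clones, 6 with no filter, 4 with summed counts, 5, 4 and 5 without numbers 1, 3 and 4, and 1 with the limit. Genes in all 4 pairs were 6 higher and 3 lower with no filter and 0 and 0 in 4 separate fits of 3 against 3. Between title numbers DESeq2 called 10 genes in wild type and 17 in knockout, and single clones left out gave 0 to 0 and 0 to 1 (1 without 4J). The reversals concerned uncalled genes. With single clones left out, log2 fold changes ran from -0.69 (without 3G) to 1.29 for Csf1r, from -0.145 to 0.102 (without 4K) for Mpo, from -0.006 (without 1A) to 0.161 for Cd34, from -0.0548 (without 1A) to 0.0843 for Bcl2l1, from -4.11 to 0.0904 (without 2D) for S100a9 and from -4.27 to 0.653 (without 2D) for Ltf. Mpo was also above 0 without 1A, 2D, 2F or 3I. Csf1r had -0.22 with the voom block, -0.235 with voom alone and -1.02 without number 3. Bcl2l1 had -0.0415 without number 1, Mcl1 0.0157 and Ltf 0.324 without number 2. With the Hoxb8 covariate the values were 2.06 for S100a9, 2.29 for Ltf, 0.0272 for Mpo, -0.0165 for Cd34 and 0.0041 for Hoxb8 itself. Except for fits on fewer clones or with a limit on size, the cause was not tested. At this depth and number of clones, changes in a ratio of 5 to 4 were mostly missed in simulated data, with 15 of 50 recovered.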

Other observations

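The gene families and the per-clone patterns in this part were chosen after the data were seen. Gene families taken by name extended the picture of amino acid supply and translation, with edgeR's adjusted p over all genes for members and an exact permutation test of clone scores adjusted over 10 families. Of 20 cytosolic aminoacyl-tRNA synthetase genes, which charge tRNAs, 11 were higher in knockout and 0 lower (adjusted p = 0.0217 for clone scores). Only 2 of 6 knockout clones scored above every wild-type clone for this family. Of 17 mitochondrial synthetase genes 0 were higher (adjusted p = 0.485 for clone scores). Some of these cytosolic genes were also in the ATF4-CHOP list. Of 22 amino acid transporter genes 10 were higher and 0 lower, of which Slc3a2, Slc7a1, Slc7a5 and Slc7a11 were also in the ATF4-CHOP list, and 6 of 6 knockout clones scored above every wild-type clone (adjusted p = 0.0216). Cytosolic ribosomal protein genes were higher in 28 of 80 and lower in 0 (38 higher and 2 lower when adjusted over the list alone), by a median log2 fold change of 0.12, and 4 of 6 knockout clones scored above every wild-type clone (adjusted p = 0.0216). A slightly different set of ribosomal protein genes, without Rplp0, Rplp2 and Rpsa, was used for the share of counts. This share was 1.98% ± 0.0813 in knockout and 1.80% ± 0.0628 in wild type (exact permutation p = 0.00433, adjusted over 6 library measures 0.026). Reads shared with ribosomal pseudogenes are missing from these counts, so the levels are uncertain.

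Of 36 proteasome subunit genes 6 were lower and 0 higher, with 33 of 36 log2 fold changes below 0 (adjusted p = 0.0216). Of 12 fatty acid synthesis genes Scd1, Scd2, Fads2 and Acly were lower and 0 higher (9 lower when adjusted over the list alone, adjusted p = 0.0216 for clone scores). Scd1, a stearoyl-CoA desaturase gene, was at 20.9 CPM ± 26.5 in wild type and 1.08 CPM ± 1.31 in knockout. Cdk6 and Cdkn1a were higher among 12 genes of the INK4-ARF and RB pathway (adjusted p = 0.0216), and Cdkn2a was at 1.88 CPM ± 3.84 and 6.72 CPM ± 4.98 (edgeR adjusted p = 0.376). Mitochondrial ribosomal protein genes were lower in 5 of 76 and higher in 0 (adjusted p = 0.347), histone genes higher in 2 of 34 and lower in 0 (adjusted p = 0.346), and 0 of 7 chaperonin genes were called (adjusted p = 0.347).

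Reads assigned to Hoxb8 and to Esr1, the estrogen receptor alpha gene, went together over the 12 clones, and the counts do not separate reads of the transgene from those of the endogenous genes (Pearson r = 0.998, Spearman rho = 0.958, permutation p = 1e-05 for each, the smallest they can give). Without the 2 clones farthest from the median r was 0.988, and within genotypes it was 0.999 in wild type and 0.992 in knockout. Hoxb8 ranged from 65.2 CPM in 4L to 253 CPM in 2D, and the ratio of Esr1 to Hoxb8 counts only from 1.19 to 1.34. Clone 2D, with the highest level, also had the highest levels of S100a9 and Ltf.

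In single clones some genes were far lower than in all others. Counting genes at 5 CPM or more in 11 clones and at least 10 times lower in the remaining clone, 12 were found in 2D, 8 in 4J, 3 each in 1B, 2F and 3I, 2 each in 1A, 1C, 4K and 4L, 1 each in 2E and 3H and 0 in 3G. Rab31 was at 1.23 CPM in 4J and at 178 CPM or more elsewhere. Tfpi had 0 counts in 4J, where 3 counts correspond to 0.127 CPM, and at least 56.2 CPM elsewhere. Dynlt3 on the X chromosome was at 0.036 CPM in 1B and at least 65.1 CPM elsewhere, Tdrkh at 0.038 CPM in 1A and at least 41 CPM elsewhere, and Isyna1 at 9.20 CPM in 1C and at least 149 CPM elsewhere.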
